A study of Homo sapiens with 6 samples.

How the data were processed

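RNA-seq was available for 6 libraries of the BJ cell line, 3 given a control siRNA and 3 an siRNA against agrin, grouped and numbered by the labels. Per the labels' protocols, total RNA was isolated with a Zymo Quick-RNA kit and libraries were made with the TruSeq Stranded mRNA kit. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The sequence of the siRNAs, the dose and the time of collection are not given in the sources used here.

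The deposited table gives 1 column per library of a normalized expression signal for 14168 genes by symbol, which its name calls CPM. Per the submitters' processing notes, STAR 2.6.1d, SAMtools, HTSeq and edgeR were used with build hg38. The annotation release, the strand setting of the counting, the filter on genes and the normalization factors are not given in the sources used here. The deposited columns sum to between 1073190 and 1096530, so they are scaled by a library size other than the total of the listed genes. Every value in a column was a whole multiple of 1 step (100% of values, tolerance 0.01 of a read), and dividing by that step gave whole reads, 42736368 to 48246613 per library. The columns hold no rows without a gene name, and 100 listed genes are at 0 in all 6 libraries. In the text, scaled CPM means these deposited values.

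The design had been set for CPM values. The unit found was a scaled CPM, for which the same test was kept. Genes with a value of at least 1 in at least 3 libraries were tested (13206 genes) on log2(value + 0.5) with limma 3.58.1 in R 4.3.3, with a trend in the variance prior, no covariate and Benjamini-Hochberg adjustment; genes with an adjusted p under 0.05 in this two-sided test were called. Fold changes are on the log2(value + 0.5) scale, which understates the change of low genes. The 3 libraries of one group did not overlap those of the other for 3754 of the called genes and for 45.2% of all tested genes, where chance gives 10%. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 4.44 to 5.88 among controls and 10.3 to 24.9 among agrin siRNA libraries).

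Of 40 gene lists fixed before the data were examined, the 35 with at least 5 tested members were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. For each list the calls over all genes and those adjusted over the list alone were counted. The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took AGRN; the 12 largest increases and 12 largest decreases among called genes with a mean of at least 5 in the higher group and no overlap between groups, without unnamed loci and pseudogenes; up to 4 called members per list with the largest change, or the 2 most abundant members where fewer than 2 were called; and the 3 most abundant genes. For lists past the list threshold the members so taken are named, and for the other lists the first of them; some genes the rule took are not reported here. Genes printed outside this rule were chosen after their values were seen: AL645608.5, ISG15, PMVK, FADS1, FADS2, SREBF1, ACACA, FASN, ELOVL5, ACSL3, PLIN2, PLIN3, CPT1A, ATF5, STC2, CHAC1, TNFAIP6, ICAM1, TNFAIP2, ZMAT3, ADAMTS5, FAP, ADAMTS12, SGCB, LRP4, DAG1, MT1L, ROBO4 and the genes of the closing observations.

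Symbols were matched to GENCODE release 29 on GRCh38 for coordinates and gene types, and 14144 of 14168 matched 1 gene. Genes with near-identical copies, such as HLA, tubulin, AKR1C, metallothionein and ribosomal protein genes, are uncertain where counting could split their reads, as are overlapping and antisense genes, since the strand setting is not known. At this depth 3 reads correspond to a value between 0.0681 and 0.0761.

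The test was run on simulated reads for the 13206 genes with 200 genes changed between the agrin siRNA and control groups. It recovered 50% of 50 genes changed 1.2-fold, 98% of 50 changed 1.5-fold and 100% of those changed 2-fold or 3-fold, with 13 false calls among 187 (6.95%). The simulation changed far fewer genes than were called in the data and drew genes independently, so these shares may not hold there. Alternatives were pseudocounts of 0.1 and 1, no filter and a mean of at least 5, median-of-ratios, quantile and rescaled values, limma without trend, robust or with array weights, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, stricter thresholds, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.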

Results

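Polyadenylated RNA was sequenced from 6 libraries of BJ cells, an established line of human foreskin fibroblasts. The cells had been given a control siRNA (3 libraries) or an siRNA against agrin (3 libraries). Agrin, encoded by AGRN, is a secreted heparan sulfate proteoglycan of basement membranes, known for clustering acetylcholine receptors at the neuromuscular junction. The libraries held between 42736368 and 44139864 reads on listed genes in the control group and between 44321473 and 48246613 in the agrin siRNA group. COL1A2, COL1A1 and FN1, which encode chains of type I collagen and fibronectin, were the 3 most abundant transcripts and together took 4.08% of all reads. The mitochondrially encoded transcripts took 0.493% ± 0.00951 of the reads in the control group and 0.474% ± 0.0204 in the agrin siRNA group (SD, n = 3 each). On the first principal component, with 68.2% of the variance, the control libraries lay between -15.1 and -11.9 and the agrin siRNA libraries between 13.1 and 15.4. The agrin siRNA libraries also differed among themselves on the second component, with 16.5% of the variance, where replicate 1 lay at 10.8, replicate 2 at -12.7 and replicate 3 at 1.79.

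The single comparison of the series asked which transcripts changed with the siRNA against agrin. RNA was measured, so the level of agrin protein is not known. AGRN itself fell by 63.6% in the agrin siRNA libraries. Nearly every gene of cholesterol synthesis fell with it, together with most of the amino acid response genes tested, among them PSAT1 and PHGDH of serine synthesis, and SCD, the desaturase that makes monounsaturated fatty acids. Most interferon-induced genes and most p53 target genes tested rose, and so did the chemokines CXCL1 and CXCL6 and the secreted proteases MMP1, MMP3 and PLAU.

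AGRN stood at 744, 804 and 790 scaled CPM in control replicates 1, 2 and 3, and at 290, 297 and 265 in agrin siRNA replicates 1, 2 and 3. The means were 779 ± 31.6 and 284 ± 16.6 (SD, n = 3 each), so 36.4% ± 2.13 of the control level was left. These values rest on 11679 to 32495 reads per library. The log2 fold change of AGRN was -1.46 with a standard error of 0.05 (limma, adjusted p = 3.19e-06), and no other gene had a smaller p-value. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1. AGRN (ENSG00000188157.14) spans positions 1020123 to 1056118 of chromosome 1 on the plus strand of GRCh38. AL645608.5, an annotated sense intronic transcript at positions 1055033 to 1056116 within AGRN and on its strand, was lower too (log2 fold change -1.32, limma adjusted p = 9.22e-06), but it overlaps AGRN, so its reads are uncertain. ISG15, an interferon-induced ubiquitin-like protein whose gene ends at position 1014540 just before AGRN, was higher (log2 fold change 0.69, limma adjusted p = 0.00142).

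**Figure D1:**
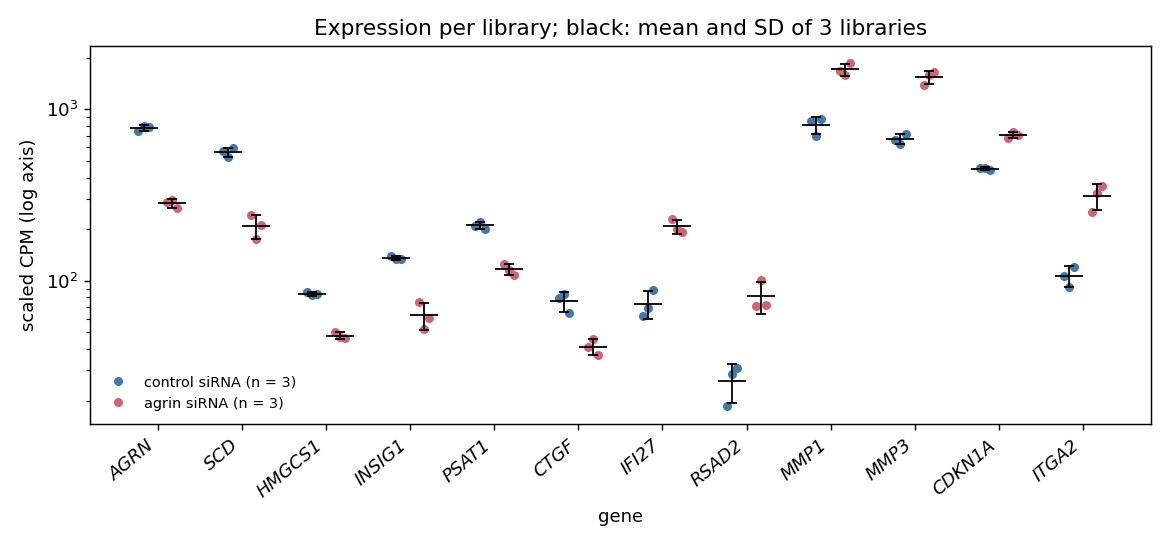
Scaled CPM (log axis) of 12 genes in each of the 3 control siRNA and 3 agrin siRNA libraries; points are libraries, and black marks are the mean and SD of 3 libraries. AGRN lay between 744 and 804 in the control libraries and between 265 and 297 in the agrin siRNA libraries.

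Of 13206 genes tested, 2005 were higher and 1783 lower in the agrin siRNA libraries at an adjusted p under 0.05 (limma), which is 28.7% of the genes. Most of these changes were small, with a median fold of 1.21, and 42 genes rose and 45 fell by at least 2-fold. ACAN, the core protein of the cartilage proteoglycan aggrecan, had the largest decrease, from 17.2 ± 1.93 to 1.35 ± 0.761 scaled CPM (SD, n = 3), a log2 fold change of -3.33 (limma adjusted p = 1.83e-05). SCD fell from 564 ± 34.7 to 209 ± 33.0 (log2 fold change -1.44). Other large decreases were in C10orf105 (-1.99), the protease inhibitor A2M (-1.94), CLUL1 (-1.76), the fatty acid binding protein FABP3 (-1.72) and the glutamate receptor subunit GRIA1 (-1.66). They continued with the matricellular protein TINAGL1 (-1.65), the GTPase activating protein ARHGAP26 (-1.60), the collagen chain COL21A1 (-1.51) and the ligand WNT11 (-1.51). The longest annotated 3' UTRs of ACAN and ARHGAP26, and those of TGFB2, IGF2 and COL12A1, carry the sequence TGCCCTTG. Of the 653 genes with this sequence 25.0% were lower, against 13.1% of genes without its last 7 bases, a gap that other motifs also show. Among genes with a mean of at least 5 in the higher group, the largest increase was in ANGPTL4, a secreted inhibitor of lipoprotein lipase, from 1.19 ± 0.222 to 8.30 ± 0.777 (SD, n = 3), a log2 fold change of 2.38 (limma adjusted p = 6.26e-06). The pentraxin NPTX1 (2.00) and the EGF receptor ligand AREG (1.78) came next, then the interferon-induced genes OASL (1.77), RSAD2 (1.64), IFI27 (1.50) and HERC5 (1.40). ITGA2, the collagen-binding integrin subunit, rose from 106 ± 14.9 to 312 ± 54.4 (1.54) and C3, the central complement component, from 198 ± 13.5 to 550 ± 59.1 (1.47). CEND1 (1.39), SPHKAP (1.33) and the small GTPase RRAD (1.33) completed the 12 largest increases among genes with such a mean and no overlap between the groups. On the recovered reads, edgeR called 1844 genes higher and 1887 lower, of which 3621 had the same call as in limma. The counts of higher and lower genes were 1121 and 940 without control replicate 1, 1257 and 1063 without control replicate 2, and 1251 and 1118 without agrin siRNA replicate 3. Without control replicate 3 they were 1350 and 1264. Without agrin siRNA replicate 1 they were 1977 and 1811, and without agrin siRNA replicate 2 they rose to 2538 and 2586. Rescaling the libraries without mitochondrial genes and the 10 most abundant genes gave 1574 higher and 2260 lower genes, so the higher genes made up 41.1% of the calls instead of 52.9%.

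**Figure D2:**
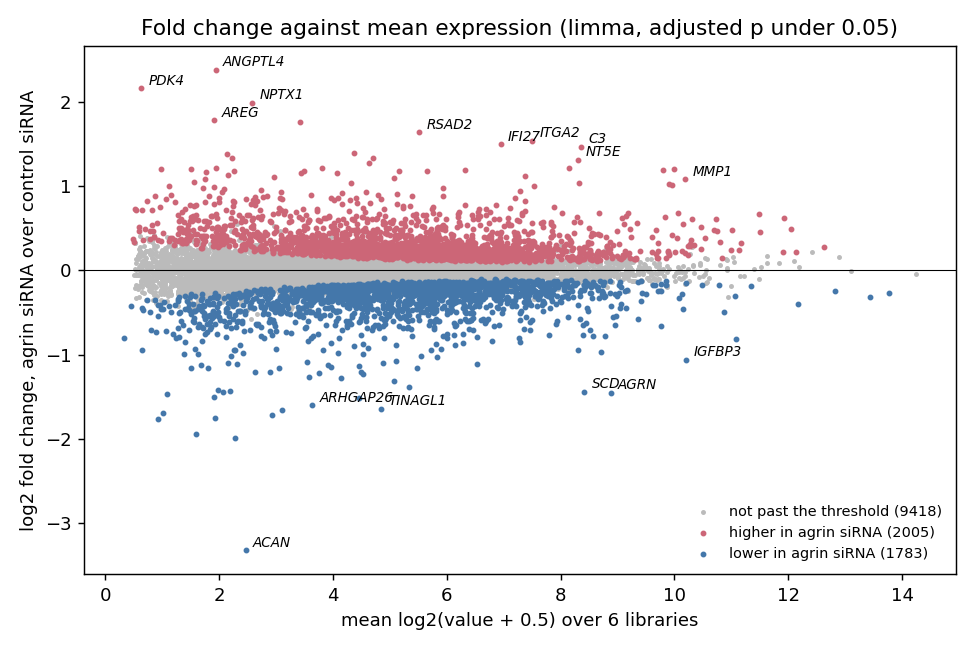
Log2 fold change of agrin siRNA over control siRNA (vertical axis) against mean log2(value + 0.5) over the 6 libraries (horizontal axis) for 13206 tested genes; red points are the 2005 genes higher and blue points the 1783 genes lower at an adjusted p under 0.05 in limma. AGRN and SCD lie among the most abundant of the genes with large decreases.

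Genes of cholesterol synthesis fell together. Of 25 tested, 24 were lower and 0 higher, and 24 were lower when adjusted over the list alone; PMVK, a kinase of the mevalonate pathway, did not pass (0.03, limma adjusted p = 0.723). INSIG1, the endoplasmic reticulum protein that retains SREBP, had a log2 fold change of -1.12. HMGCS1 and MSMO1, enzymes of the pathway, followed at -0.80 and -0.79. The median over the list was -0.56 (camera adjusted p = 2.73e-17; adjusted p = 0.496 with an estimated correlation).

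Among 20 genes of fatty acid metabolism and lipid storage, 8 were lower and 6 higher. The lower genes were SCD (-1.44), FADS2 (-0.77), SREBF1 (-0.60), ACACA (-0.60), FADS1 (-0.60), FASN (-0.58), ELOVL5 (-0.39) and ACSL3 (-0.30), which encode enzymes that make, desaturate, elongate or activate fatty acids and a transcription factor of lipid synthesis. The higher genes were ANGPTL4 (2.38), PDK4 (2.17), PPARG (0.83), PLIN2 (0.46), CPT1A (0.31) and PLIN3 (0.17), among them the carnitine transferase of fatty acid oxidation, lipid droplet coat proteins and a kinase that restrains pyruvate oxidation. PDK4 stood at only 0.241 scaled CPM in the control group, and its log2 fold change ran from 1.62 with a pseudocount of 1 to 3.56 with DESeq2 over the alternatives that tested it. Adjusted over the list alone, 8 were higher and 9 lower. The list did not pass by camera (adjusted p = 0.419) and passed by fry (adjusted p = 0.0444).

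Genes of the amino acid response, many of them targets of the transcription factor ATF4, were mostly lower. Of 28 tested, 18 fell and 3 rose (20 and 3 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 3.33e-06; adjusted p = 0.848 with an estimated correlation). PSAT1 (-0.85) and PHGDH (-0.69) are enzymes of serine synthesis, CTH (-0.72) makes cysteine from cystathionine, and ALDH1L2 (-0.59) belongs to mitochondrial folate metabolism. The higher members were ATF5 (0.31), STC2 (0.33) and CHAC1 (0.34). Among 23 chaperones and regulators of endoplasmic reticulum stress, 12 rose and 2 fell (12 and 5 adjusted over the list alone). HSPA5, the main chaperone of that compartment, was at 0.38, CALR, calreticulin, at 0.33 and MANF at 0.31, while DDIT3, the stress transcription factor CHOP, was at -0.44. The list missed the threshold (camera adjusted p = 0.0571) and passed it without agrin siRNA replicate 1 (adjusted p = 0.0292) and without agrin siRNA replicate 3 (adjusted p = 0.043).

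Interferon-induced genes rose. Of 37 tested, 31 were higher and 0 lower, and 35 were higher when adjusted over the list alone. OASL (1.77), RSAD2 (1.64), IFI27 (1.50) and HERC5 (1.40) led the list; RSAD2 encodes the antiviral protein viperin, and HERC5 the ligase that attaches ISG15. RSAD2 went from 26.0 ± 6.63 to 81.6 ± 17.2 scaled CPM and IFI27 from 73.6 ± 13.7 to 207 ± 19.6 (SD, n = 3). The list median was 0.53 (camera adjusted p = 2.24e-13; adjusted p = 0.848 with an estimated correlation). Relative to the control mean, the list median was 0.47, 0.70 and 0.40 in agrin siRNA replicates 1, 2 and 3, and -0.20, 0.07 and 0.11 in control replicates 1, 2 and 3.

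Inflammatory genes rose more often than they fell. Of 33 NF-kB targets and secreted inflammatory factors, 19 were higher and 4 lower (21 and 5 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000184; adjusted p = 0.848 with an estimated correlation). The chemokines CXCL1 (1.22) and CXCL6 (0.93) and the growth factor CSF3 (0.97) rose, and the adhesion receptor VCAM1 fell (-1.16). TNFAIP6 (-0.38), ICAM1 (-0.30) and TNFAIP2 (-0.20) were the other lower members. The 3 immune cell markers tested were also higher, too few for a list test. CD68, a lysosomal protein of macrophages that the control fibroblasts also expressed at 131 ± 9.09 (SD, n = 3), had a log2 fold change of 1.00. CD74 (0.72) and CD14 (0.59) were near the filter, at 0.875 and 1.51 in the control group, and all 3 were higher when adjusted over the list alone.

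Targets of the tumour suppressor p53 were mostly higher. Of 25 tested, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 1.63e-08; adjusted p = 0.282 with an estimated correlation). TP53I3 (0.66), the cyclin-dependent kinase inhibitor CDKN1A (0.65), the p53 ubiquitin ligase MDM2 (0.56) and the death receptor FAS (0.54) had the largest changes, and the lower member was ZMAT3 (-0.16). CDKN1A went from 451 ± 7.21 to 707 ± 26.8 scaled CPM (SD, n = 3). Of 34 genes of G2/M and mitosis, 1 was higher, PTTG1 (securin, 0.33), and 1 lower, UBE2C (a ubiquitin-conjugating enzyme of mitotic exit, -0.35), and 0 passed when adjusted over the list alone. The list median was -0.15 and the list was called lower (camera adjusted p = 0.0361; adjusted p = 0.959 with an estimated correlation), but the median was -0.05 without agrin siRNA replicate 1 and -0.31 without agrin siRNA replicate 2. That call was lost without control replicate 2 (adjusted p = 0.133), control replicate 3 (0.132), agrin siRNA replicate 1 (0.678) or agrin siRNA replicate 3 (0.172), and rescaling without mitochondrial and top genes also ended it (0.0698). UBE2C and PTTG1 each lost their own call when single libraries were left out, with adjusted p up to 0.122 without agrin siRNA replicate 3 and 0.123 without control replicate 1. Among 34 genes of G1/S and DNA replication, 2 were higher and 3 lower (2 and 1 adjusted over the list alone), with MCM6, a helicase subunit, at -0.38 and the sliding clamp PCNA at 0.38 (camera adjusted p = 0.745).

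Matrix proteases and their inhibitors rose more often than they fell. Of 23 tested, 12 were higher and 3 lower (13 and 4 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00151; adjusted p = 0.496 with an estimated correlation). MMP3, stromelysin, went from 669 ± 44.0 to 1543 ± 134 scaled CPM and MMP1, interstitial collagenase, from 807 ± 94.1 to 1707 ± 139 (SD, n = 3), log2 fold changes of 1.20 and 1.08. The plasminogen activator PLAU (1.04) and its inhibitor SERPINE2 (1.03) rose by similar amounts, and ADAMTS5 (-0.47), FAP (-0.45) and ADAMTS12 (-0.20) fell. Among 39 collagens and other fibrillar matrix genes, 14 were higher and 10 lower (15 and 11 adjusted over the list alone; camera adjusted p = 0.58, fry adjusted p = 0.0247). Tenascin C, TNC, rose (1.01) with COL6A1 (0.62; 0.40 after quantile normalization), and COL12A1 (-0.81) and COL11A1 (-0.71) fell.

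By camera, the lists of agrin partners, basement membrane, heparan sulfate and integrin genes did not pass, and by fry the heparan sulfate list did (fry adjusted p = 0.0173). Of 8 tested agrin receptors and partners, SGCB, a dystrophin complex subunit, passed the threshold (0.16, limma adjusted p = 0.0351), and 0 passed when adjusted over the list alone (camera adjusted p = 0.911). ITGB1, the most abundant of them, was at 0.13 (limma adjusted p = 0.295; 0.0277 without agrin siRNA replicate 1), and ITGAV at -0.04 (limma adjusted p = 0.829). LRP4, the agrin receptor of muscle, was at 0.06 (limma adjusted p = 0.632), and DAG1, dystroglycan, at -0.05 (limma adjusted p = 0.448). Of 20 basement membrane genes, 5 were higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.911), with COL15A1 at -0.84 and the laminin chain LAMA2 at -0.64. Of 26 heparan sulfate proteoglycans and synthesis enzymes, 6 were higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.911). The sulfatases SULF2 (-0.58) and SULF1 (-0.50) and the glypican GPC6 (-0.53) fell, and the sulfotransferase HS6ST1 rose (0.47). Of 27 integrin and focal adhesion genes, 5 were higher and 5 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.88), with ITGA2 at 1.54, ITGA3 at 0.71, ITGB3 at 0.63 and ITGA4 at -0.65.

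The list of Hippo pathway components was called lower by camera and not by fry. Of 24 tested, 0 were higher, 8 lower and 16 not past the threshold (0 higher and 10 lower adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0033; adjusted p = 0.848 with an estimated correlation) and of -0.09 without agrin siRNA replicate 1. AMOT, a scaffold that binds YAP, was at -0.64, WWTR1, which encodes the co-activator TAZ, at -0.41 and the TEAD cofactor VGLL4 at -0.25. VGLL3, another TEAD cofactor, was at -0.42 (-0.28 without agrin siRNA replicate 1), and its call was lost without each library except agrin siRNA replicate 2, with adjusted p from 0.0705 without control replicate 3 to 0.147 without control replicate 2, and also with no filter, without the variance trend, with edgeR and with DESeq2. The 21 YAP and TAZ targets went both ways, with 8 higher and 6 lower (8 and 9 adjusted over the list alone; camera adjusted p = 0.776). NT5E, the ectonucleotidase CD73, rose (1.31), and the growth factor TGFB2 (-1.14), the binding protein IGFBP3 (-1.06) and CTGF (-0.87) fell. Of 22 contractile genes and targets of SRF, 4 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.58), with FHL1 at -0.64 and the smooth muscle actin ACTG2 at 0.38. Of 27 genes of actin nucleation and its regulation, 6 were higher and 6 lower (8 and 6 adjusted over the list alone; camera adjusted p = 0.88), with ARHGEF2 at -0.37 and WASF1 at -0.33.

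The list of targets of bone morphogenetic proteins (BMPs) was called higher. Of 15 tested, 6 were higher, 0 lower and 9 not past the threshold (7 higher and 1 lower adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0133; adjusted p = 0.496 with an estimated correlation) and of 0.12 without control replicate 3. The BMP antagonist NOG (1.20) and the transcriptional regulators ID1 (0.73), ATOH8 (0.56) and ID2 (0.54) had the largest changes. Early response genes and regulators of FGF and EGF signalling were called higher, with 10 of 26 higher and 5 lower (11 and 5 adjusted over the list alone) and a median of 0.12 (camera adjusted p = 0.0377; adjusted p = 0.848 with an estimated correlation). The EGF receptor ligands AREG (1.78) and EREG (1.12) and the early response gene PHLDA1 (0.76) rose, and so did IER3 (0.70), whose call was lost without control replicate 2 (adjusted p = 0.0521). The list lost its call without control replicate 2 (adjusted p = 0.0532), control replicate 3 (0.0794), agrin siRNA replicate 1 (0.095) or agrin siRNA replicate 3 (0.0544), with no filter (0.0678) and with a filter on a mean of at least 5 (0.179), and its median was 0.21 without agrin siRNA replicate 2. Of 18 TGF-beta targets, 5 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.611, fry adjusted p = 0.0376), with NEDD9 at -1.26, PODXL at 1.20 and BHLHE40 at -1.10. Of 11 Wnt targets and inhibitors, 3 were higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.949), with WNT2 at -1.38 and the feedback inhibitor AXIN2 at -1.11. Of 13 genes of the insulin-like growth factor axis, 1 was higher, the protease PAPPA (0.94), and 5 lower, with IGF2 at -0.92 (2 and 5 adjusted over the list alone; camera adjusted p = 0.484).

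The list of nuclear genes of oxidative phosphorylation was called higher. Of 31 tested, 9 were higher, 0 lower and 22 not past the threshold (13 higher and 0 lower adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.000817; adjusted p = 0.848 with an estimated correlation). COX6A1 (0.27), NDUFB3 (0.26), NDUFV2 (0.23) and NDUFA1 (0.22), subunits of the oxidase and of complex I, changed most. The trends of fold change on GC content and exon length given under the other observations were not removed for this list. Of 13 mitochondrially encoded transcripts, 0 were higher and 3 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.419), with MT-CO3 at -0.23 and MT-ATP8 at -0.20, the latter not called without control replicate 1 (adjusted p = 0.0521). Of 26 hypoxia and glycolysis genes, 4 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.862), with ALDOC at -0.37 and the glucose transporter SLC2A1 at -0.36, the latter not called without control replicate 1 (adjusted p = 0.0657). Of 21 NRF2 targets, 3 were higher and 7 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.419), with the reductase AKR1C1 at 1.19 and the cystine transporter SLC7A11 at -0.48. Of 5 metallothionein list members, MT1L rose (0.53; 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.745), and the abundant MT2A was at 0.11 (limma adjusted p = 0.151; 0.0351 without agrin siRNA replicate 3). Of 29 lysosome and autophagy genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.88), with the protease CTSS at 1.18. Of 42 ribosomal protein genes, 2 were higher and 6 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.321), with RPS19 at 0.22, not called without control replicate 1 or 3 (adjusted p = 0.0642 and 0.0726). That list was called lower without control replicate 3 (adjusted p = 0.0401), without agrin siRNA replicate 1 (0.00635) and after quantile normalization (0.0472). Of 13 genes of the small RNA silencing machinery, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.635). TNRC6C, a partner of Argonaute proteins, was at -0.53 and TARBP2 at 0.20, the latter called in the full data and lost without 5 of the 6 libraries, with adjusted p up to 0.115 without control replicate 1.

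By camera, no tested list of markers of fibroblasts or of other cell types passed, and by fry the keratinocyte and epithelial list did (fry adjusted p = 0.00182). Of 21 fibroblast markers, 5 were higher and 7 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.88), with NT5E at 1.31, S100A4 at 0.64, DPP4 at 0.58 and CD34 at -0.46. Of 9 keratinocyte and epithelial markers, 3 were higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.88), with the tight junction protein CLDN1 at 1.27 and the laminin chain LAMB3 at 0.67. Of 9 pericyte and smooth muscle markers, 4 were higher and 3 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.88), with CSPG4 at 0.53 and NDUFA4L2 at -0.68. The endothelial, skeletal muscle, melanocyte and neural lists had 3 or fewer tested members and no list test. ROBO4 was the 1 of 3 endothelial markers that rose (0.55), TNNT1 the 1 of 2 skeletal muscle and synapse markers (0.45) and TUBB3 the 1 of 3 neural and Schwann markers (0.74), with the same 1 of each when adjusted over the list alone. Of 3 melanocyte markers, KIT (-0.45) and MITF (-0.23) were lower (2 adjusted over the list alone), and both calls were weak. KIT lost its call without any 1 of control replicates 1 and 2 and agrin siRNA replicates 1 and 3 (adjusted p up to 0.137), and MITF without each library except agrin siRNA replicate 2, with no filter and without the variance trend (adjusted p up to 0.148).

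**Figure D3:**
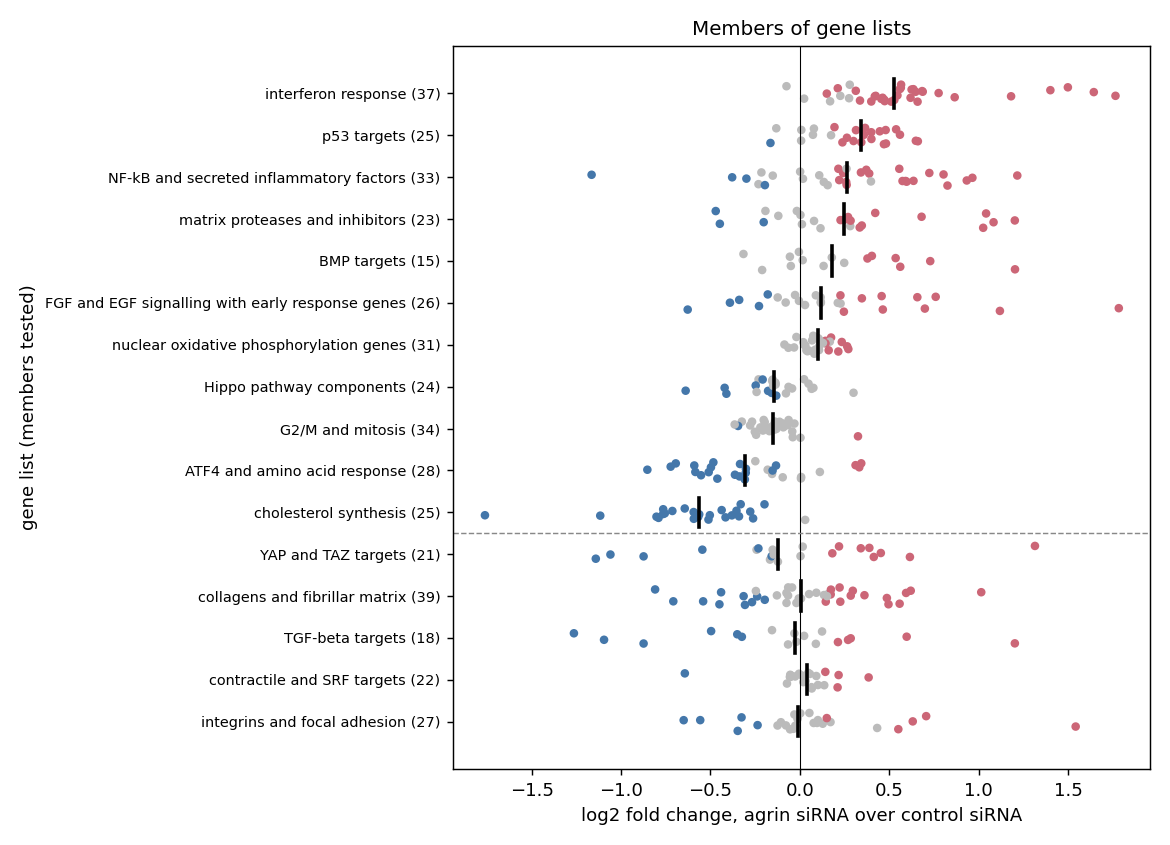
Log2 fold change of agrin siRNA over control siRNA for each tested member (points) of the 11 gene lists past the list threshold (above the dashed line) and of 5 lists that were not (below it); red points were higher, blue points lower and grey points not past the threshold, and black bars are list medians. The cholesterol synthesis median lies at -0.56 and the interferon response median at 0.53.

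By camera with its preset correlation, 7 of 35 tested lists were higher and 4 lower. With an estimated correlation 0 were past the threshold. By fry, which asks whether a list's members move one way on balance, 14 passed. Unlike camera, fry does not compare a list with other genes. The Hippo list (fry adjusted p = 0.0755) and the G2/M list (0.644) passed by camera and not by fry. The median, the mean and the camera direction differed in sign for 10 lists that did not pass, namely agrin partners, heparan sulfate, basement membrane, integrins, Wnt, fatty acid, lysosome, fibroblast, keratinocyte and pericyte genes.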

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

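One alternative, leaving out genes that carry a 7-base motif described under the other observations, was chosen after seeing the data. It gave 1824 higher and 1436 lower genes. The AGRN decrease was past the threshold under all 19 alternatives that refit it, with log2 fold changes from -1.54 to -1.41 and adjusted p of at most 0.000145. The counts of higher and lower genes stayed within 1.5 times of 2005 and 1783 under the pseudocounts, filters, scalings, variance models without array weights, edgeR and DESeq2 (1744 and 1689). Array weights gave 4114 and 4152, with a warning from limma that the weights had not converged, and the cause was not tested. Leaving out each library in turn gave 1121 to 2538 higher and 940 to 2586 lower genes, with fewer libraries tested. The highest counts came without agrin siRNA replicate 2, so fewer libraries did not always mean fewer calls. An adjusted p under 0.01 left 1020 and 909 genes, and a log2 fold change of at least 1 left 42 and 45, by construction. With an estimated correlation between genes, camera called 0 lists higher and 0 lower, against 7 and 4, where the unadjusted p was under 0.05 for p53 targets (0.00805) and matrix proteases (0.0432), and fry called 14. Neither p of fry compares a list with other genes. By its mixed p, which has no direction, 31 lists passed, against 11 by camera. Of the 11 lists called, 9 kept their call under all 17 other camera fits; the G2/M list (adjusted p up to 0.678) and the FGF and EGF list (up to 0.179) did not. None of these fits removed the trends on GC content and exon length described under the other observations. List medians after their removal were obtained for the cholesterol and interferon lists only, so the other calls were not checked against these trends.

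Of 147 called genes among those the rule took, 121 kept their call under every alternative that refit them. Over all 155 genes and their alternatives, 2802 of 2913 values stayed on the same side of the threshold, 104 lost the call, 6 gained one and 1 reversed. Of the 2802, 11 had the opposite direction to the main test, with no call in either fit. The reversed one was ACTB, at 0.22 in the main test (adjusted p = 0.038) and -0.039 after quantile normalization (adjusted p = 0.637, the highest over its alternatives); the cause was not tested. Of 664 list values, 629 stayed on the same side of the threshold, 24 lost and 11 gained a call, and 0 reversed with a call in either fit. Of the 629, 24 had the opposite direction to the main test, with no call in either fit.

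The replicate numbers were checked as possible pairs. Deviations from the group means of same-numbered libraries correlated at -0.037, 0.175 and 0.202 across genes. The values for replicates 2 and 3 were the highest of all pairs, while control replicate 1 correlated best with agrin siRNA replicate 3 (0.147). The correlations were weak and do not settle whether the numbers mark pairs. With the replicate number as a block, 1905 genes were higher and 1775 lower, and no list or named gene changed its call. AGRN rests on at least 11679 reads per library, while the values of CD74, PDK4 and PODXL lie near the filter of 1 in at least 1 group.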

Other observations

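The additional gene groups, and the tests of other splits, of a partial motif source, of single libraries and of a response to the siRNA itself, were chosen after the results were seen; since some members of each group had already been seen to change, the groups are described without a group test. Of 15 genes of MHC class I antigen presentation tested, 12 were higher in the agrin siRNA libraries and 0 lower (limma), with a median of 0.31. HLA-B rose by 0.67 on the log2 scale, from 2276 to 3638 scaled CPM, TAP1, a peptide transporter, by 0.58 and B2M, the light chain of the complex, by 0.28 from an already high level of 5770, though HLA genes share reads. Of 12 genes of fatty acid oxidation and targets of PPAR transcription factors, 8 were higher and 1, FABP3 (-1.72), was lower. Beyond ANGPTL4, PDK4, PLIN2 and CPT1A, described in the report, the higher genes included ACADVL (0.52) and SLC25A20 (0.51), a mitochondrial dehydrogenase and the carnitine carrier of long-chain fatty acids.

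Of 11 tubulin genes, 9 were higher and 0 lower, among them TUBB3 (0.74), TUBA1A (0.45) and TUBB6 (0.41), with the caution that near-identical copies share reads. Of 15 circadian clock genes, 8 were lower and 1 higher. The lower ones included BHLHE40 (-1.10), PER3 (-0.54), NR1D2 (-0.41), TEF (-0.38) and CRY1 (-0.24), repressors or output factors of the clock, and the higher one was the activator ARNTL (0.33). Of 7 EGF family ligands, receptors and regulators, 5 were higher and 0 lower. Besides AREG (1.78) and EREG (1.12), these were the ERBB ligand NRG1 (0.67), HBEGF (0.35) and the receptor EGFR (0.25).

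A search of 15677 7-base motifs in the 3' UTRs of 11764 tested genes was made for matches to a short siRNA seed. The longest annotated 3' UTR of each gene was used, and which 3' UTRs these cells express was not determined. GCCCTTG had the lowest t for fold change, with 22.7% of genes that carry it lower and 11.8% higher, against 13.1% and 16.2% of genes without it. The next motif, TGCCCTT, overlaps it, and of the 653 genes with the joined TGCCCTTG 25.0% were lower and 9.65% higher. ACAN (-3.33), ARHGAP26 (-1.60), TGFB2 (-1.14), IGF2 (-0.92) and COL12A1 (-0.81) are among the lower ones. GCCCTTG occurs in coding exons 5 and 19 of the AGRN-201 transcript (7323 nucleotides), at transcript positions 994 and 3308. These are chromosome 1 positions 1041389 to 1041395 and 1046827 to 1046833 of GRCh38, within CAAGAAGTTCGACGGCCCTTGT and TCTGGGGGGCTCGAGCCCTTGG. Other motifs were also more frequent in lower genes than in genes not past the threshold, TTGTTTT with 62.0% against 46.1% and TATTTAT, the motif with the highest t, with 45.5% against 36.3%, so the raw gap is not particular to GCCCTTG; the t values allow for the length and GC content of the 3' UTR. In AGRN-201 the base before GCCCTTG is G at position 994 and A at position 3308, so the joined TGCCCTTG does not occur in it. Of all tested motifs 26.5% occur in this transcript, and the siRNA sequence is not given in the sources used here. On shuffled fold changes of the same comparison the search found 19 of 20 motifs planted with a shift of 0.04. The shift was equal in all carriers and shuffling removed any co-regulation of genes, so recovery in the real data may be lower.

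The first pattern is the number of genes past the threshold, 3788, most with small changes. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; 1 split, the real one, gave 3788 genes, and the highest of the others gave 0. Fold changes had a rank correlation of 0.27 with GC content and of -0.23 with exon length across genes, which are not independent replicates, but 3996 genes passed after loess trends on both were removed, 3093 of them with the same call as before, which argues against those trends as the whole cause. Direct silencing of other transcripts through the siRNA seed is a candidate source of part of the lower genes. The t of GCCCTTG, -6.43, lay below the lowest of 100 permutations of the genes, -4.99. The permutations and the 95% interval that follows treat genes as independent, although co-regulated genes are not. The tables argue against direct matches to this 1 motif as the main source, since lower genes carried the motif 8.41 percentage points more often than genes not past the threshold (95% interval 6.35 to 10.5; 20.6% against 12.2%), while weaker matches to other seeds and indirect effects of such silencing stay open. Of all tested motifs only 2, GCCCTTG and the overlapping TGCCCTT, had a t below the lowest of the permutations, so no other seed stood out. The sources used here do not say whether the agrin siRNA is 1 duplex or a pool, which would bring several seeds.

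The second pattern is the decrease of cholesterol synthesis genes. The list median stayed at -0.56 or lower under 3 other scalings (-0.5632 was the value nearest to 0), so it did not depend on the choice among them. These scalings left the median log2 fold change of all genes between -0.0273 and 0.000237. They could hardly have removed the decrease and do not test scaling as its cause. The list median was -0.5576 after GC and length trends were removed. Direct matches to GCCCTTG are not needed: 23 of the 25 members lack GCCCTTG in their longest annotated 3' UTR and had a median of -0.51. A response of SREBP-driven transcription to agrin loss, weaker matches to other seeds and indirect effects of the siRNA on a regulator of these genes all stay open. The first could be tested by restoring an AGRN transcript that the siRNA does not match and measuring INSIG1 and HMGCS1.

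The third pattern is the rise of interferon-induced genes. The list median was at least 0.426 without any 1 of the 6 libraries, so no single library accounts for the rise. It was at least 0.50 under 3 other scalings. These left the median log2 fold change of all genes between -0.0273 and 0.000237, so they could hardly have removed the rise and do not test scaling as its cause. A response to the siRNA duplex itself, as a double-stranded RNA, and a response to agrin loss cannot be told apart, because the labels name 1 agrin siRNA condition and the control siRNA libraries show only what another duplex does. As for the cholesterol genes, indirect effects of the siRNA on a regulator stay open too. A second agrin siRNA of another sequence could test part of this. If it lowered AGRN without raising these genes, agrin loss alone would not account for the rise. If it raised them, a response to a duplex and a response to agrin loss would both stay open.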
